A study of Mus musculus with 2 samples.

How the data were processed

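Long-read RNA sequencing was carried out on gastrocnemius, the large calf muscle of the hind limb, from male B6CASTF1/J mice aged 2 months. These mice are first-generation hybrids of the C57BL/6J and CAST/EiJ inbred strains. The labels describe 2 libraries made from 2 µg of RNA each, replicate 1 and replicate 2, and number the males differently although both carry the same donor identifier. They form a single group, so no condition was compared with another and no p-value was computed. The spread between the libraries is that between these samples and includes technical variation.

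Per the file headers and the notes deposited with each library, reads were aligned to the mouse genome build mm10 and assigned to GENCODE M21 transcripts or to unannotated models by TALON, 1 library at a time, and the authors deposited whole-number read counts per transcript model without normalisation. The aligner, tool versions and filters are not given in the sources used here. Each model carries a class that the authors' annotation step assigned: annotated transcript, incomplete splice match (part of an annotated intron chain), a chain that joins annotated splice sites in an unannotated way, a chain with an unannotated splice site, genomic (overlapping a gene without matching its splice junctions), antisense and intergenic. Such processing can move reads between classes: short exons can be lost when long reads are aligned, truncated molecules become incomplete splice matches, and reads of near-identical copies can be given to different models. Only models with at least 1 read were listed. The labels name ERCC and SIRV spike-in RNAs; reads of the ERCC kind were kept apart from all library sizes, and the SIRV kind was not analysed here.

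The depth was 1132759 endogenous reads in replicate 1 and 1449423 in replicate 2. Counts were summed per annotated gene and expressed as counts per 1000000 reads of annotated genes (CPM). A gene with 0 reads could have a level of up to 3 counts, or 2.71 CPM in replicate 1 and 2.14 CPM in replicate 2. Shares of reads have Wilson 95% intervals, and values of both libraries are given as mean ± SD (n = 2). The reads carry no molecular identifiers, so intervals and floors cover counting error only. The chi-square statistic of the 2 count columns was 6.21 per degree of freedom over 8626 genes, so the libraries differed by more than sampling noise and were counted separately.

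The following choices were made before the data were examined. Fast and slow fibre paralogs were compared as log2 of the read ratio with a prior count of 0.5, and a ratio was said to exceed the spread when it had the same sign in both libraries and its mean lay over 2 SD from 0. Of 26 gene lists, each list's median log2 ratio of replicate 2 over replicate 1 was taken over members with at least 10 summed reads. Its percentile was read among 10000 random lists of the same size and of matched mean expression, as a description of these libraries. Genes over 2-fold apart were counted among those with at least 50 summed reads, and 100 Poisson draws gave the count from sampling alone. Isoform shares were computed without genomic reads for genes with at least 20 reads in each library. Unannotated chains were matched between the libraries by chromosome, strand and exact intron chain. Named genes were the 20 with the highest mean CPM, the myosin heavy chain genes, the fast and slow pairs, up to 4 leading members of each list, up to 15 preset isoform genes with the most reads, the 10 unannotated spliced chains with the most reads, the 10 genes most apart in each direction and the 5 most read unannotated loci. A number of smaller values under this rule were left out for length, and some members of the lists are not reported here.

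Other choices were made after the data were seen. Internal exons were scored as included or skipped by the reads that span them; cassette exons were annotated exons over 30 nt in the preset isoform genes with a mean inclusion of 10 to 90%. Constitutive exons, those in every annotated transcript that spans them, were scored by length. Coding genes with at least 200 summed reads were ranked by fold as well, and the reads of other models on the same strand within 1000 bp were added to each gene. Random lists were matched within 20 bins of expression. Slopes on length have bootstrap intervals from 2000 draws.

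The alternatives fixed in advance were other scalings (median-ratio size factors and the TMM factors of edgeR), other count minimums, annotated transcripts only, no genomic reads, no mitochondrially encoded genes, thinning of the deeper library, another prior count, other isoform thresholds and leaving out each library. Simulated counts were drawn by Poisson sampling, with no variation between libraries beyond counting error. On such counts 4245 genes of the real libraries reached at least 50 summed reads, and changed genes below that minimum were not scored. Among the 4245, 93 of 93 genes changed 3-fold and 84 of 84 changed 4-fold were recovered as over 2-fold apart, with 10 of 4068 unchanged genes. Of 200 simulated unchanged lists 14 (7.0%) fell outside the central 95%, and 20 of 20 doubled lists did. The real libraries differed by more than sampling noise, so these rates need not hold for them. The computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.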

Results

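Transcripts of adult mouse gastrocnemius, a mixed but mainly fast hind limb muscle, were counted from long reads in 2 libraries of a single group. Replicate 1 held 1182747 reads and replicate 2 held 1480977. Spike-in RNAs took 4.23% and 2.13% of them. Of the endogenous reads, 97.7% and 96.8% were assigned to annotated genes. Annotated genes with reads numbered 12755 in replicate 1 and 13485 in replicate 2, and 7881 had at least 5 reads in each library. Across the 4294 genes with at least 50 summed reads, which are not independent replicates, Spearman's rho between the libraries was 0.907 and Pearson's r of the log2 values was 0.940.

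Most endogenous reads matched an annotated transcript, and a single calcium pump gene supplied most of the reads with an unannotated splice site. Annotated transcripts held 64.0% ± 0.934 of endogenous reads (SD, n = 2), and chains with an unannotated splice site held 16.8% ± 0.0219. Atp2a1, which encodes the sarcoplasmic reticulum calcium pump SERCA1 of fast fibres, accounted for 82.0% of the reads of that class in replicate 1 and 80.4% in replicate 2. Without Atp2a1, an alternative chosen after seeing the data, the class held 3.69%. Incomplete splice matches held 9.88% ± 0.333, and chains joining annotated splice sites in an unannotated way held 3.97% ± 0.125. Of the incomplete splice matches, 67.3% and 71.6% lacked the 5′ part of the annotated chain. Those that the authors' classes call prefixes of the chain made up 19.4% and 14.5%, and Aldoa, a glycolytic aldolase gene, supplied 78.6% and 68.7% of these. Genomic reads made up 2.30% (Wilson interval 2.27 to 2.32) in replicate 1 and 2.98% (2.95 to 3.00) in replicate 2. Antisense reads made up 1.70% (1.67 to 1.72) and 2.66% (2.63 to 2.68), so both shares were higher in replicate 2 by more than counting error. Intergenic reads made up 0.480% ± 0.0376. Protein-coding genes held 98.4% ± 0.0224 of the reads of annotated genes.

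**Figure D1:**
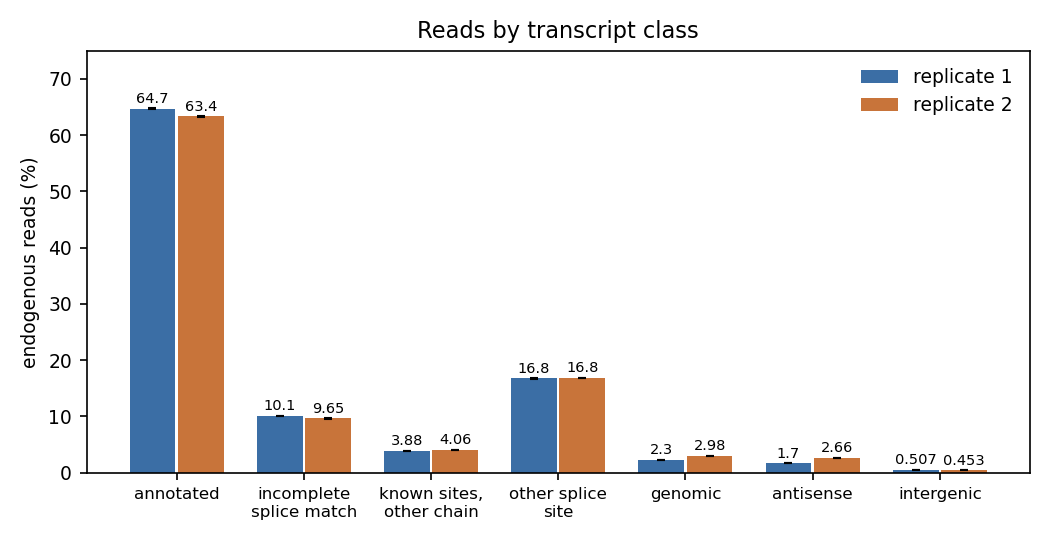
Endogenous reads by transcript class, in percent, for each library, with bars for the share and error bars for the Wilson 95% interval. Annotated transcripts held 64.7% and 63.4%, and chains with an unannotated splice site held 16.8% in both libraries.

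Genes of contraction, calcium uptake and energy supply dominated both libraries. Atp2a1 alone reached 146178 ± 1805 CPM (SD, n = 2), or 14.6% ± 0.181 of the reads of annotated genes. Ckm, the muscle creatine kinase that regenerates ATP from phosphocreatine, followed with 68626 ± 6255 CPM, and Acta1, the skeletal muscle actin, with 57232 ± 6175 CPM. Next came Tnnc2, the calcium-binding troponin C of fast fibres, with 25849 ± 5304 CPM and Tpm1, an actin-binding tropomyosin, with 21674 ± 5789.9 CPM. The 20 leading genes together took 47.2% of the reads in replicate 1 and 41.6% in replicate 2.

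The other leading genes fell into the same groups. Thick and thin filament genes were Myh4, the myosin heavy chain of type IIB fibres (16698 ± 2546 CPM), the myosin light chain genes Mylpf (11134 ± 3574 CPM) and Myl1 (11057 ± 3435 CPM), Mybpc2, the fast myosin-binding protein C (5805 ± 1017 CPM), and Tnni2, the fast troponin I (4307 ± 1786 CPM). Z-disc and cytoskeletal genes were Actn3, the alpha-actinin of fast fibres (10495 ± 2783 CPM), Tcap, which caps titin (6434 ± 882 CPM), and Des, the intermediate filament protein desmin (3939 ± 215 CPM). Glycolysis was represented by Aldoa (15171 ± 4176 CPM), the enolase gene Eno3 (7785 ± 405 CPM), the lactate dehydrogenase gene Ldha (7499 ± 460.3 CPM) and the pyruvate kinase gene Pkm (4338 ± 745 CPM). The mitochondrial ADP/ATP carrier gene Slc25a4 had 10518 ± 1051 CPM, the adenylate kinase gene Ak1 had 5138 ± 552 CPM, and Casq1, which encodes the calcium store protein calsequestrin, had 4156 ± 657 CPM.

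The fibre type genes showed a muscle dominated by fast type IIB transcripts in both libraries. Myh4 held 87.0% (Wilson interval 86.5 to 87.4) of 18968 myosin heavy chain reads in replicate 1 and 69.4% (68.9 to 69.8) of 37420 in replicate 2, a mean of 78.2% ± 12.4. Myh1, the type IIX gene, held 7.22% and 14.3%, and Myh2, the type IIA gene, held 2.64% and 5.35%. Myh7, the slow type I gene, held 2.94% (2.71 to 3.19) and 10.6% (10.3 to 11.0). Myh4 led in both libraries by more than the spread. Myh1 (mean 10.8% ± 5.03) was above Myh7 (6.79% ± 5.45) in each library, with separate Wilson intervals of 6.86 to 7.60% and 14.0 to 14.7% for Myh1.

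Other members of the family were rare. Myh14, a non-muscle myosin gene, held 0.232% and 0.249%. The embryonic gene Myh3 had 0 and 14 reads, and the neonatal gene Myh8 had 0 and 1. Myh6, the cardiac alpha gene, had 1 and 5 reads, and Myh7b had 1 and 11. Myh13 and Myh15 had 0 reads in both libraries, which allows shares of up to 0.0158% and 0.00802%. With annotated transcripts only, the Myh4 share was 50.4% and those of Myh1, Myh2 and Myh7 were 25.9%, 6.29% and 17.3%, so the levels depend on whether reads of unannotated models are counted.

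Among 13 pairs of fast and slow fibre paralogs, the fast gene had more reads in both libraries in 13 pairs. In 12 of them the ratio exceeded the spread between the libraries. Atp2a1 over Atp2a2, the slow and cardiac SERCA2 gene, had a log2 ratio of 8.22 ± 1.14 (SD, n = 2). Casq1 over Casq2 had 7.00 ± 1.36, and Mylpf over Myl2, the fast and slow regulatory light chains, had 6.13 ± 1.19. The troponin pairs gave 5.28 ± 1.21 for Tnnc2 over Tnnc1 and 4.53 ± 1.52 for Tnni2 over Tnni1. On gene totals the exception was troponin T: Tnnt3 over Tnnt1 had log2 ratios of 1.93 and 0.04, a mean of 0.99 ± 1.34, which did not exceed the spread. Of the Tnnt1 reads, 84.7% and 90.5% (561 and 2183) belonged to a 3-exon model of the 3′ end. The 110-nt exon of Tnnt1 just upstream of that model, at chromosome 7, 4508474 to 4508583, was included in 95 and 210 reads. A 110-nt exon of Tnnt3 at 142512256 to 142512365 was included in 2044 and 1864, so Tnnt3 led more widely on these exons than on gene totals. The ratios of Tpm1 over Tpm3 (4.67 ± 1.26), Myl1 over Myl3 (4.61 ± 1.13) and Myoz1 over Myoz2 (4.34 ± 0.94) were of similar size. Lower ratios were those of Ldha over Ldhb (3.99 ± 1.29), Myh4 over Myh7 (3.80 ± 1.54), Mybpc2 over Mybpc1 (2.59 ± 1.01) and Actn3 over Actn2 (2.53 ± 1.15).

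The fast over slow ratio was lower in replicate 2 in 13 of the 13 pairs. Tnni2 exceeded Tnni1 by 48.7-fold in replicate 1 and 10.9-fold in replicate 2, and Actn3 exceeded Actn2 by 10.1-fold and 3.28-fold. With annotated transcripts only, the ratio of Atp2a1 over Atp2a2 turned to a log2 of -9.93. All Atp2a1 models other than annotated transcripts, incomplete splice matches included, were then left out. Few or no Atp2a1 reads can have remained, so the size of this value is set by the prior count and is not a measured ratio.

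**Figure D2:**
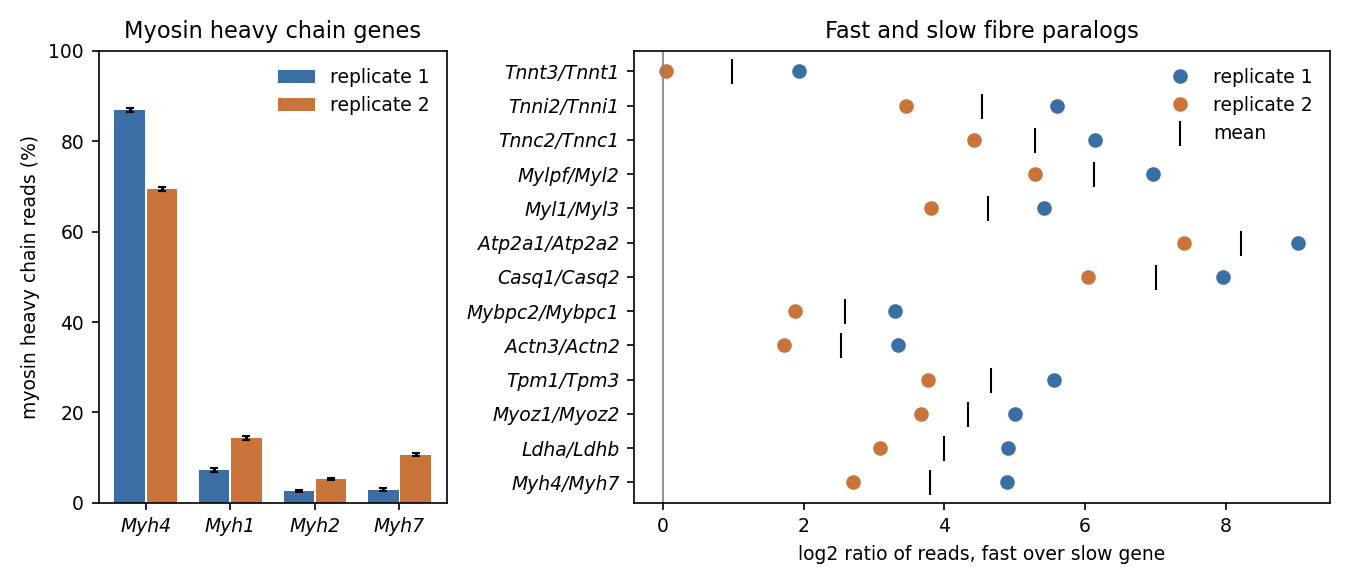
Left, reads of 4 myosin heavy chain genes as percent of all myosin heavy chain reads, with bars for each library and Wilson 95% intervals. Right, log2 ratio of reads of the fast over the slow gene for 13 pairs, with points for the libraries and a tick for the mean; 13 of 13 ratios are lower in replicate 2, and Tnnt3/Tnnt1 is nearest to 0 there.

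Lists of slow and oxidative fibre genes were higher in replicate 2, and the glycolysis list and the fast fibre list, which holds no myosin heavy chain genes, were higher in replicate 1. The fast myosin heavy chain genes Myh2 and Myh1 were higher in replicate 2 by 3.15-fold and 3.09-fold. Myh4 had a log2 ratio of 0.31, close to the median of all genes with transcripts of 4 to 6 kb (0.30) or over 6 kb (0.33). This comparison sets 1 library against 1 other and has no replicate check. Of the 26 gene lists, 12 had a median log2 ratio outside the central 95% of random lists of matched expression. The median of all genes was 0.12 on this log2 scale; median-ratio scaling lowers every log2 ratio given here by 0.10 and TMM scaling by 0.09. The medians of the 12 lists kept their signs and their side of the random lists under both scalings.

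The slow fibre list had a median of 1.26 (percentile 100 of the random lists), with 12 of 12 members higher in replicate 2 and 10 of them over 2-fold. Its leading members were Actn2 (log2 ratio 1.08), Tnnt1 (1.52), Mybpc1 (1.07) and Tpm3 (1.24). Most Tnnt1 reads belonged to the 3′-end model described above. Those that included the 110-nt exon upstream of it differed less between the libraries, with 95 and 210 reads against 664 and 2418 for the gene. The fast fibre list had a median of -0.52 (percentile 0), with 16 of 16 members lower in replicate 2 and 1 over 2-fold. Of its leading members, Mylpf (-0.67), Tpm1 (-0.55) and Tnnc2 (-0.42) were lower by more than Atp2a1 (-0.03). The myosin heavy chain list had a median of 1.66 (percentile 100), with 7 of 7 measured members higher in replicate 2, Myh7 by 5.64-fold.

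Energy metabolism split along the same line. The list of TCA cycle and fatty acid oxidation genes had a median of 0.63 (percentile 100), with 25 of 28 members higher in replicate 2. They included Fabp3, a fatty acid-binding protein gene, by 2.83-fold, and the isocitrate dehydrogenase gene Idh3a (log2 ratio 0.43). Nuclear genes of oxidative phosphorylation had a median of 0.23 (percentile 98.2), with 46 of 49 members higher in replicate 2 under scaling by totals and 38 of 49 under median-ratio scaling. Atp5b (0.48) and Cox4i1 (0.40) had the most reads. With annotated transcripts only, the percentile of this list was 96.7, and with a minimum of 50 reads it was 97.2, both within the central 95%. The glycolysis and glycogen list had a median of -0.28 (percentile 0.01), with 16 of 19 members lower in replicate 2, Aldoa (-0.57) and Pkm (-0.35) among them.

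Markers of other cell types also moved, beside these muscle groups. The tendon list had a median of 0.88 (percentile 99.7), with 6 of 8 members higher in replicate 2; Fmod, a proteoglycan gene, had 66 and 146 reads, whereas Thbs4 had 57 and 52. The erythroid list had a median of -0.74 (percentile 0.05), with 4 of 4 globin genes lower in replicate 2, Hba-a1 at 97 and 71 reads. The fibroblast and extracellular matrix list had a median of -0.22 (percentile 1.32), with 11 of 17 members lower, although Col1a1, a fibrillar collagen gene, was higher in replicate 2 (log2 ratio 0.79). The largest member, Gsn, an actin-severing protein gene, had a log2 ratio of -0.99. With annotated transcripts only, the tendon list (percentile 96.3) and the fibroblast list (5.28) came within the central 95%. No median was obtained for the tendon list with a minimum of 50 summed reads. Whether its shift holds without its less read members was therefore not tested, and Fmod and Thbs4 did not move together.

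The other 3 lists outside the random range had small medians. They were calcium handling (-0.09, percentile 2.17), ribosomal proteins (-0.09, percentile 1.22) and the preset isoform genes (-0.03, percentile 0.09). After removal of the length trend the ribosomal list came within the central 95% (percentile 5.85). Among the calcium genes Hrc, which binds calcium in the sarcoplasmic reticulum, had a log2 ratio of 0.93.

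The remaining 14 lists lay within the central 95%. Their medians were 0.32 for Schwann cells and nerve, 0.31 for the circadian clock, 0.29 for endothelium, 0.25 for muscle transcription factors and stem cells, 0.23 for smooth muscle and pericytes and 0.14 for adipocytes. Neuromuscular junction genes had 0.07, atrophy and proteolysis genes 0.01, thin filament and Z-disc genes 0.01 and immediate early and stress genes -0.01. Macrophages and leukocytes had -0.04, long non-coding RNAs -0.11, mitochondrially encoded genes -0.13 and phosphocreatine and AMP metabolism -0.20. Single members could still differ: Gabarapl1, an autophagy gene, had a log2 ratio of 1.29, Pdk4, which restrains glucose oxidation, had 1.07, and the orphan receptor gene Esrra had 1.38. With a minimum of 50 reads the atrophy and proteolysis list left the central 95% (median -0.37, percentile 0.06).

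**Figure D3:**
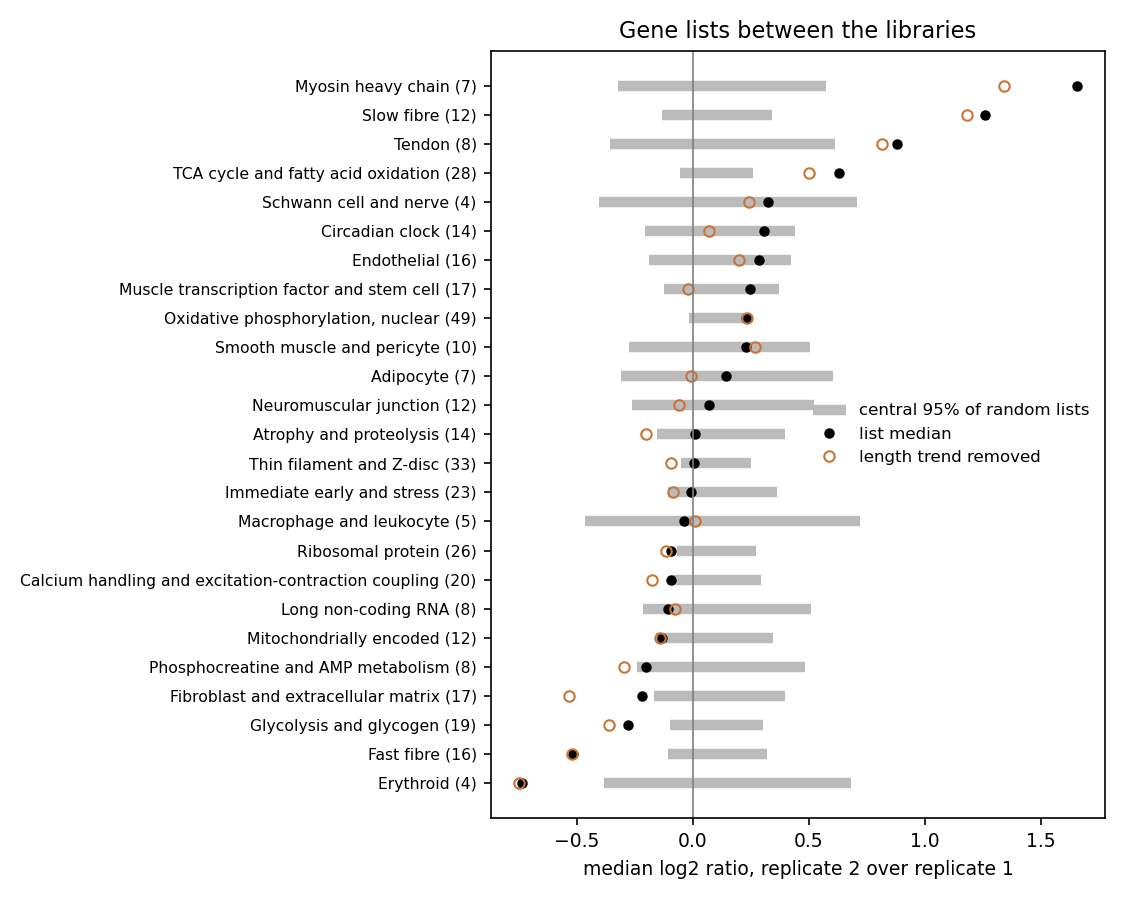
Median log2 ratio of replicate 2 over replicate 1 for 25 gene lists, with the number of measured members in parentheses. Filled points are list medians, grey bars the central 95% of 10000 random lists, and open points the medians after removal of the length trend; slow fibre (1.26) and fast fibre (-0.52) lie on opposite sides.

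At the level of single genes, 190 of 4294 (4.42%) differed by over 2-fold between the libraries. Poisson sampling alone gave a mean of 11.1 and at most 23 such genes in 100 draws. Of the 190, 167 were higher in replicate 2 and 23 in replicate 1. The split was 119 and 34 under median-ratio scaling and 124 and 33 under TMM scaling. Of 1388 coding genes with at least 200 summed reads, 51 were over 2-fold apart, and fibre type genes were among the leading ones. Myh7 had 557 and 3982 reads, Idh2, a mitochondrial isocitrate dehydrogenase gene, was higher in replicate 2 by 3.40-fold, Ldhb by 3.23-fold, Myh2 by 3.15-fold, Myh1 by 3.09-fold, Atp2a2 by 3.01-fold and Fabp3 by 2.83-fold. Parp6 (4.73-fold) and Gadd45g (3.87-fold) stood beside them. In the other direction Mss51 was higher in replicate 1 by 2.25-fold and Mylk2, the skeletal muscle myosin light chain kinase gene, by 2.10-fold. This ranking of coding genes was chosen after their values were seen.

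The most extreme folds of all belonged largely to processed pseudogenes and genes with few reads. Gm6829 had 0 and 151 reads, which is at least 39.7-fold higher in replicate 2 when 0 is set to the floor of 3 counts, and Gm45692 had 0 and 51, at least 13.4-fold higher on the same floor. The lower ends of their exact 95% intervals, which include the counting error of both libraries, were 31.9-fold and 10.5-fold. Gm12671 had 49 and 1473 reads, and Gm12033 had 936 and 20. AC154200.1 had 1 and 84 reads, a ratio of 66.3 (11.6 to 2649), and Gm6563 had 1 and 53, a ratio of 41.8 (7.19 to 1683). BC023105 had 2 and 49 reads. Among coding genes Pln, which encodes the SERCA inhibitor phospholamban of slow and cardiac muscle, had 4 and 76 reads, Nceh1 had 6 and 63, and Cdc14a had 6 and 45. Higher in replicate 1 were Styk1 (64 and 2 reads), the interferon-inducible GTPase gene Iigp1 (66 and 6), the pseudogenes Oaz1-ps (94 and 16) and Gm8116 (80 and 20), Cish, a cytokine-induced inhibitor of STAT signalling (51 and 15), mt-Rnr1 (48 and 23), Acyp2 (35 and 17), the splicing regulator Rbfox1 (69 and 34) and Rxylt1 (63 and 32).

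Reads of the pseudogenes were often found in a neighbouring model in the other library. Of 73 pseudogenes with enough reads, 10 were over 2-fold apart, and 8 of the 10 came within 2-fold when other models on the same strand within 1000 bp were added, against 6 of the 180 other genes over 2-fold apart. The sums for Gm12671 were 2125 and 1899 reads, and those for Gm12033 were 1431 and 1281. The median absolute log2 ratio of the 10 pseudogenes was 3.41 before and 0.50 after the addition. The 6 other genes included Gm45692, which overlaps Rnf170 and had sums of 72 and 89 reads, AC154200.1, which contains Oaz1-ps and had a log2 ratio of the sums of -0.27, and mt-Rnr1, with sums of 136 and 118. Values of single pseudogenes and of these overlapping or adjacent genes between the libraries are therefore uncertain.

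Most genes expressed a single main isoform, and it was usually the same in both libraries. Over 4111 genes with at least 20 reads in each library, the dominant transcript held a median of 82.0% ± 0.259 of the reads (SD, n = 2). It was the same transcript in both libraries for 3868 genes, or 94.1% (Wilson interval 93.3 to 94.8). An annotated transcript was dominant in 3702 genes (90.1%), an incomplete splice match in 137, a chain joining annotated splice sites in an unannotated way in 196 and a chain with an unannotated splice site in 76. At least 2 isoforms with 10% of the reads or more in both libraries were present in 1247 genes (30.3%). Incomplete splice matches, which can be truncated molecules, were counted as isoforms here. In Gmpr, for example, a 1-exon match of 510 nt held 37.4% and 42.2% of the reads. The count was lower with annotated transcripts only. That count varied with the settings, from 512 with a share threshold of 20% to 2109 when replicate 2 was taken alone.

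The abundant contractile and metabolic genes mostly followed this pattern. The main isoform was Ckm-203 with 94.1% and 95.7% of the reads of Ckm, Acta1-201 with 94.6% and 95.5%, Tpm1-205 with 96.5% and 96.3%, Tcap-201 with 99.9% and 99.8%, Casq1-201 with 93.6% and 93.6% and Actn3-201 with 88.7% in both. Ak1-202 had 92.2% and 91.1%, Myoz1-201 92.2% and 90.8%, and Mybpc2-201 78.5% and 83.2%. Des-201 had 90.8% (Wilson interval 89.9 to 91.6) and 97.5% (97.0 to 97.9), but these shares rest on 4193 of 4193 Des reads in replicate 1 and 4613 of 5740 in replicate 2, where the rest were genomic and left out, so no direction is drawn. Several genes split their reads. Myl1-202, with 65.4% and 62.1%, was accompanied by Myl1-201, which starts at another first exon, with 16.4% and 16.5%. Eno3-201 had 51.3% and 51.6%, beside Eno3-202 with 25.9% and 25.7%. In Aldoa a 9-exon chain classed as an incomplete splice match led with 87.3% and 81.7%, and Aldoa-201 had 4.74% and 9.93%. On chromosome 7 both ended at 126795234 on the 3′ side, whereas the chain began at 126800046 and Aldoa-201 at 126799254.

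Alternative exons of Pkm and Atp2a1 were used almost uniformly. In Pkm, whose mutually exclusive exons distinguish the M1 and M2 forms of pyruvate kinase, Pkm-202 held 90.3% and 94.9% of the reads. The exon at chromosome 9, 59675029 to 59675195 (mm10), was included in 99.6% and 99.6% of spanning reads, and the alternative exon at 59675568 to 59675734 in 0.396% and 0.378%. In Atp2a1 the 42-nt exon at chromosome 7, 126446545 to 126446586, whose inclusion marks the adult form, was included in 99.9% and 99.8%.

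Some cassette exons of the preset isoform genes differed between the libraries. Of 57 such exons in 28 genes, chosen for a mean inclusion of 10 to 90%, 12 had Wilson intervals that did not overlap between the libraries. Both 41-nt exons of Tnnt3, the fast troponin T gene, were among them: the exon at chromosome 7, 142513665 to 142513705, was included in 79.9% and 65.0% of spanning reads, and the one at 142514326 to 142514366 in 19.9% and 34.4%. These 2 exons were near complements of each other, so they are not separate observations. Neb, which encodes the thin filament ruler nebulin, had 11 such exons, of which 11 had higher inclusion in replicate 2 and 5 had separate intervals. Nearby exons of a gene can be spanned by the same reads, so the counts of exons are not counts of independent differences. A 42-nt exon of Mybpc1 at chromosome 10, 88582007 to 88582048, was included in 81.4% and 91.7%, and a 303-nt exon of Ttn, the titin gene, in 47.0% and 68.4%. Nrap, Phka1 and Srl supplied the other 3 exons, with inclusion of 67.9% and 52.7%, 67.2% and 58.3%, and 29.6% and 39.0%.

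The main Atp2a1 isoform in these files differed from every annotated one at its 5′ end. It held 94.8% (Wilson interval 94.7 to 94.9) of the spliced reads of the gene in replicate 1 and 95.6% (95.5 to 95.6) in replicate 2. Compared with Atp2a1-201 it lacked an annotated 18-nt exon at chromosome 7, 126462500 to 126462517. The first exon was extended by 26 nt, from 126462779 to 126462804, a net gain of 8 nt. The 18-nt exon was included in 0 of 158229 and 0 of 198966 spanning reads. Very short exons were often absent elsewhere too. Of 20 exons of 20 nt or less that every spanning annotated transcript contains, Atp2a1's included, 12 were included in under 50% of reads, against 4 of 19596 exons of 61 to 200 nt. Those of 14 nt or less, in Capn1, Capn2, Ksr1, Pitpnb, Tnni2, Tnnt1 and Tnnt3, had 0% inclusion. Those of 17 to 20 nt were mixed. Besides Atp2a1, those of Hacd1, Chmp1a, Suds3 and Trim44 had a mean of at most 1.99%, whereas those of Denr, Ik, Nap1l1, Rnf185, Rnf5 and Sugt1 had at least 92.7%. Some short exons were retained: an 18-nt exon of Atp2a2 at chromosome 5, 122500931 to 122500948, was included in 96.2% and 94.6%, and an 18-nt exon of Trdn, the triadin gene, in 96.8% and 99.3%.

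**Figure D4:**
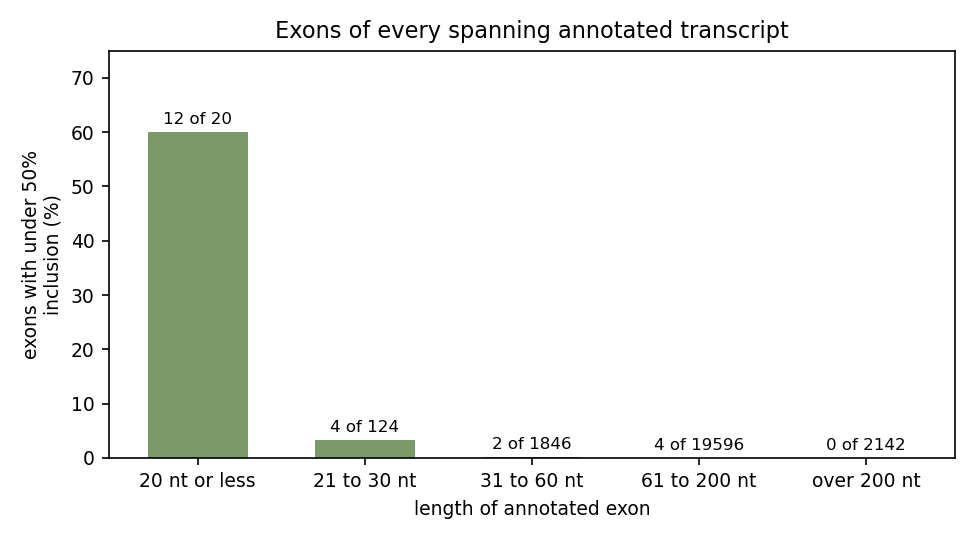
Percent of constitutive annotated exons with under 50% inclusion, as the mean of both libraries, by exon length; the numbers over the bars are exons under 50% of all exons in the bin. Exons of 20 nt or less show 12 of 20 under 50%, and exons of 61 to 200 nt show 4 of 19596.

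Unannotated spliced chains were shared in part between the libraries. Chains with at least 2 reads in each library numbered 3688, which is 62.7% of such chains of replicate 1 and 44.7% of those of replicate 2. The number was 8567 with at least 1 read and 1440 with at least 5. After Atp2a1, the most read was a Myh4 chain with an added 326-nt first exon at chromosome 11, 67237508 to 67237833, upstream of the annotated start, with 32.7% and 31.5% of the gene's reads. A Tnni2 chain held 65.9% and 58.5%. It had added 5′ exons relative to the closest annotated transcript, Tnni2-203, but only 1 of its introns was unannotated in the gene. That intron, at chromosome 7, 142442499 to 142443170, spans an annotated 7-nt exon that was included in 0 of 5573 and 0 of 3733 reads. Chains of Srl, the sarcalumenin gene, and Vdac3, a mitochondrial channel gene, differed from the closest annotated transcript by junction shifts of 3 nt and 1 nt and held 53.7% and 49.3%, and 92.2% and 87.4%. An Oaz1 chain, from the ornithine decarboxylase antizyme gene, lacked an annotated 4-nt intron and held 96.0% and 94.7%. Chains of Ndrg2 (44.7% and 36.8%) and of Idh3b, an isocitrate dehydrogenase subunit gene (89.5% and 85.9%), differed at a first and a last junction. In Bin1, which shapes the T-tubule membrane, a chain with an added 45-nt exon at chromosome 18, 32423242 to 32423286, held 64.9% and 62.7%. The last of the 10 was a second Atp2a1 chain with 498 and 524 reads.

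The share of incomplete splice matches and the difference between the libraries both varied with transcript length. Incomplete splice matches made up 6.48% ± 1.05 of the reads of genes under 1 kb and 30.6% ± 1.66 of those over 6 kb (SD, n = 2). Genes of longer transcripts had higher ratios of replicate 2 over replicate 1: the median log2 ratio was -0.05 under 1 kb, 0.23 from 3 to 4 kb and 0.33 over 6 kb. The slope over genes to 6 kb was 0.0868 log2 per kb (bootstrap interval 0.0752 to 0.0981), and that to 2 kb was 0.0347 (-0.0157 to 0.0816). Over 39 spike-in RNAs of up to 1.99 kb the slope was -0.227 (-0.492 to 0.215). Slow and fast fibre lists differed by 1.78 in their medians, and by 1.70 after removal of the length trend, an alternative chosen after seeing the data but before this difference was computed.

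**Figure D5:**
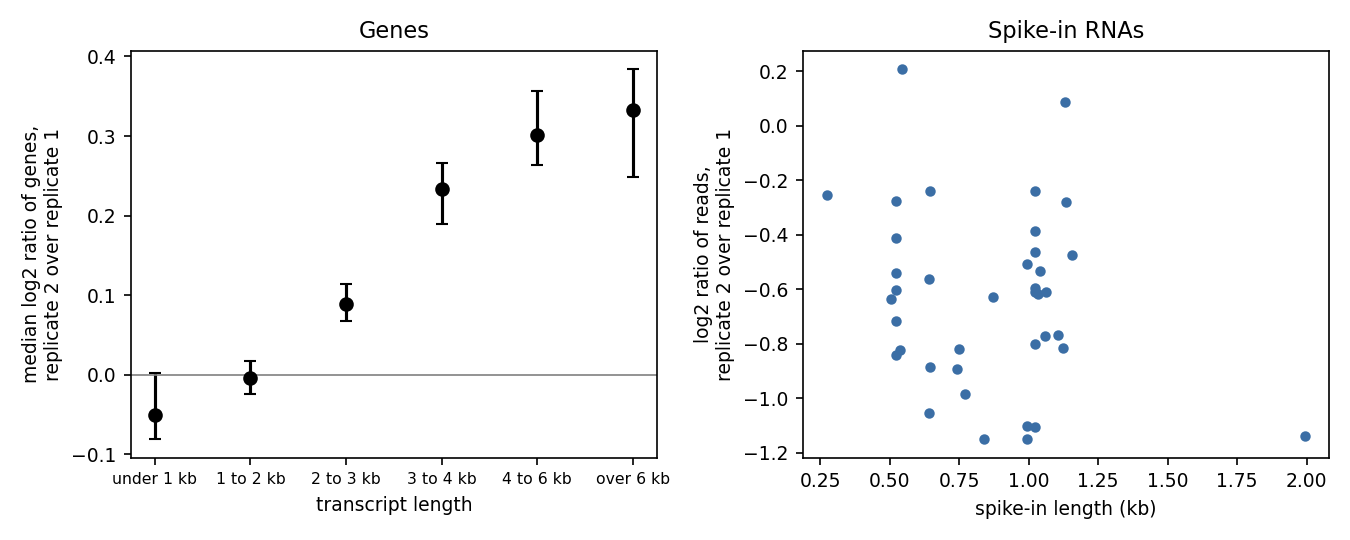
Left, median log2 ratio of replicate 2 over replicate 1 for genes by transcript length, with bootstrap 95% intervals, from -0.05 under 1 kb to 0.33 over 6 kb. Right, log2 ratio of reads against length in kb for 39 spike-in RNAs, each a point.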

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

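The ratio of antisense to sense shares in the most read genes was set as a test before its value was seen; the spike-in control of strand was chosen only after the result was seen. Reads outside the genes compared above were singled out because they exceed the limit that a count of 0 allows; the series has no control samples. Spike-in RNAs took 4.23% of all reads in replicate 1 (Wilson interval 4.19 to 4.26) and 2.13% (2.11 to 2.15) in replicate 2.

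The 5 most read unannotated loci found in both libraries lay opposite or next to annotated genes, in mm10 coordinates of replicate 1; the models of the libraries overlap but do not share both ends. On chromosome 17, an antisense locus from 39843013 to 39846245 opposite the long non-coding RNA gene Gm26917 had 2119 reads, and in replicate 2 the locus reached 39848035 and had 4623 reads, whereas Gm26917 itself had 7 and 13. On chromosome 9, a locus from 77656524 to 77660127 opposite Klhl31, a muscle kelch-like protein gene, had 2238 and 3781 reads (start 77656631 in replicate 2) against 89 and 113 for Klhl31. A locus opposite Cdv3, also on chromosome 9, from 103354101 to 103355313, had 245 and 562 reads (start 103354469 in replicate 2) against 39 and 53 for Cdv3. An intergenic locus on chromosome 4, from 91851487 to 91851668, abutting the pseudogene Gm12671, had 2076 and 426 reads. Another on chromosome 11, from 20334834 to 20335012, abutting the pseudogene Gm12033, had 495 and 1261 reads.

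Reads on the strand opposite to an annotated gene were too unevenly spread for a strand error that strikes all reads at a fixed rate. The 100 most read genes held 58.8% and 54.6% of sense reads but 1.92% and 1.60% of antisense reads, a ratio of at most 0.0327. The spike-in control of misassigned strand decided nothing: 0 spike-ins had reads on both strands, so choosing those with sense reads fixed their antisense share at 0. With the 5 and 4 spike-ins that had antisense reads only (359 and 248), the share was 0.718% and 0.786%. An error confined to some loci or to unspliced molecules stays open, since single-exon models held 95.8% and 96.7% of the antisense reads. No biological explanation was tested.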

How the results depend on the processing

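Removing the length trend from each list, leaving out Atp2a1 and summing models within 1000 bp were tests chosen only after the result was seen, although the difference of the fibre lists without the trend was set before its value was seen; the other alternatives were fixed before the data were examined. Of the alternatives to the main results, 67 stayed within the spread or within 1.5 times and 30 moved; of those to single genes and lists, 389 stayed, 95 moved and 1 reversed. The cause of these moves was not tested unless given. For class shares, gene levels, myosin shares and pair ratios, leaving out a library could not exceed the spread. With 2 libraries each value lies within the SD of their mean, so these settings counted as staying by construction and say nothing about stability. Without genomic reads, annotated transcripts held 65.8%, chains with an unannotated splice site 17.3% and incomplete splice matches over 6 kb 32.9%; without mitochondrially encoded genes the second was 16.9%. Without Atp2a1 the shares of annotated transcripts, incomplete splice matches, annotated sites joined in an unannotated way and unannotated sites were 74.6%, 11.0%, 4.50% and 3.69%, since the gene's main chain belongs to the last class. With annotated transcripts only, the 20 leading genes held 37.7%, and Myh4, Myh1, Myh2 and Myh7 held 50.4%, 25.9%, 6.29% and 17.3% of myosin reads. Atp2a1 over Atp2a2 then reversed to -9.93, because every Atp2a1 model other than an annotated transcript was excluded, not the main chain alone. Few or no Atp2a1 reads can have remained, so the size of this value is set by the prior count. Under the same setting the dominant transcript held 99.8%, was shared in 98.2% of genes, and 581 genes had several isoforms. Genes over 2-fold apart numbered 538 with a minimum of 20 reads and 53 with 200, since the genes counted change. With 50 reads per library the dominant transcript held 85.6%, was shared in 95.6% and 614 genes had several isoforms; without incomplete splice matches the first 2 values were 90.3% and 95.6%; a share threshold of 20% left 512 genes. Shared unannotated chains numbered 8567 with 1 read and 1440 with 5. With length taken from the most read annotated transcript, incomplete matches over 6 kb were 21.9%. Leaving out each library gave 80.6 to 81.6% for the dominant transcript and 1688 to 2109 genes with several isoforms; without replicate 1 the latter rose above 1.5 times the main count, as both the read minimum and the share are then needed in 1 library only. Between 9 and 12 gene lists lay outside the random range under each alternative. With models within 1000 bp summed for every gene, 179 of the 4294 genes were over 2-fold apart (176 of the 190 and 3 others). The fast gene was higher in 11 to 13 pairs, counted beyond the spread, or by sign alone when a library was left out. Single-read models were 60.6% and 60.2% of all models, and whether depth sets this share was not tested. No paired analysis was possible because the series holds a single group.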

Other observations

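The micro-exon and spike-in slope tests and the fibre list comparison were set before their values were seen, whereas the tests of a parental variant and of coding length in Atp2a1 were chosen only after the result was seen. Members of lists given above only by their medians had the following levels. Among endothelial genes Rgcc had 97.6 ± 5.15 CPM (SD, n = 2), and Aqp1, a water channel gene, had 59.3 ± 4.25 CPM. The myelin genes Pmp22 and Mbp had 45.9 ± 8.69 and 31.2 ± 5.76 CPM. Of the clock genes Tef had 205 ± 1.97 CPM and Dbp had 102 ± 8.41 CPM, both close in the 2 libraries. At the neuromuscular junction Rapsn, which clusters acetylcholine receptors, had 43.2 ± 2.38 CPM. The imprinted non-coding RNA gene H19 had 123 ± 21.8 CPM, and Ighm, an immunoglobulin gene, had 238 ± 54.3 CPM. The mitochondrially encoded gene mt-Co1 had 1009 ± 65.5 CPM.

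The Atp2a1 chain that lacks the 18-nt exon may reflect a very short exon lost in alignment. In other genes, annotated internal exons of 60 to 200 nt had a median inclusion 100 percentage points above that of exons of 20 nt or less. That gap cannot decide, since only 19 of the 119 short exons were found in every spanning annotated transcript. The others may be skipped whether or not alignment loses exons. Of the 19, 11 were under 50%, with 0% inclusion at 14 nt or less and mixed values at 17 to 20 nt. A variant of the CAST parent would be carried by reads of 1 parental allele, but the chain held at least 94.8% of the reads in each library. A coding isoform without the exon would keep the reading frame, yet the change in coding length leaves a remainder of 2 when divided by 3. The retained 18-nt exons of Atp2a2 and Trdn show that loss is not general at that length, and the reads themselves were not examined.

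The fold between the libraries varies with transcript length, and both a length bias between the libraries and a difference in the fibre type composition of the piece of muscle may contribute. Length bias cannot be told apart here: the spike-in slope of -0.227 per kb had an interval (-0.492 to 0.215) that included both 0 and the slope of the genes, and only 1 spike-in was near 2 kb. The fibre lists differed by 1.70 after removal of the length trend, outside the range of random list pairs (-0.35 to 0.33), so the trend did not account for that difference. Whether fibre composition in turn produces the trend over all genes was not tested. Different pieces of the muscle, the animals and the library preparation remain possible sources, untested.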
